A study of Mus musculus with 9 samples.

How the data were processed

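Gene expression was measured by RNA sequencing in colonic epithelial cells of 9 wild-type C57BL/6J mice. Per the labels' protocols, the cells were isolated with magnetic beads as negative for CD45, a marker of leukocytes, and positive for EpCAM, a marker of epithelium. The 3 groups were Healthy (no dextran sodium sulfate), DSS (colitis induced with dextran sodium sulfate, DSS, a polymer that injures the colonic epithelium) and DSS_AcBb (DSS after gavage with the gut bacteria Anaerostipes caccae and Bifidobacterium bifidum). Each group had 3 mice, 1 library per mouse, and each mouse was treated as a separate replicate because the titles number separate mice. Per the labels' protocols, male mice aged 6 weeks drank amoxicillin at 1 g/L for 6 days, received 2 gavages of both bacteria, drank 2.5% DSS for 7 days and were sampled on day 9. All samples carry the same protocol text, so whether the Healthy mice also drank amoxicillin is not clear from it.

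Libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name the mouse build mm10, HISAT2, an aligner, and StringTie, a transcript assembler. They give no versions and no strand setting for the counting. The deposited table holds 3 values per gene and library. The read counts deposited by the authors are whole numbers with no normalization, per the file headers and the values. The FPKM values deposited by the authors are scaled by transcript length and by library size, per the file headers. The TPM values deposited by the authors are scaled to a common total in each library, per the file headers. Only the read counts were used here. The table holds 16124 genes, and its lowest count is 1, so a gene with no read in any 1 of the 9 libraries is missing from it. Cell types that are rare among the sorted cells are therefore covered by few of their markers. A gene silent in 1 or more Healthy libraries is missing too, even if colitis turned it on. Positions were matched by gene ID to the RefSeq annotation of GRCm38.p6, the assembly on which mm10 is based, and were found for 15272 of the genes tested.

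Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its default minimum of 10 reads, which left 15301 genes. Those removed held at most 0.00884% of the reads of any library. Library sizes were scaled by the trimmed mean of M values (TMM). A quasi-likelihood negative binomial model with robust estimation was fitted to all 9 libraries, with 1 mean per group. The contrasts DSS minus Healthy, DSS_AcBb minus DSS and DSS_AcBb minus Healthy were tested 2-sided with the quasi-likelihood F-test. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05, without a minimum fold change. Normalised read counts are given as CPM, the reads of a gene scaled to a common library size after TMM, as the mean ± SD of 3 libraries. Fold changes are log2 values. Their standard error (SE) was calculated back from the fold change and the p value of the F-test, so it restates that p value. Depth ranged from 43877370 to 62696344 counted reads per library. The SE and the tests carry both the counting error at that depth and the spread between mice. Shares of reads carry 95% Wilson intervals, which cover counting error only, because reads amplified by PCR are not independent molecules.

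The genes named in the text were chosen by a rule set before the data were examined. For DSS minus Healthy and for DSS_AcBb minus DSS it took the 10 higher and the 10 lower called genes with the largest absolute log2 fold change. They had to reach a group mean of 5 CPM in the higher group, to show no overlap between the libraries of both groups, and to be neither predicted genes nor antigen receptor segments. Where fewer than 5 passed in a direction, the 5 genes with the smallest p in that direction were taken, under the same limits on level and name. They are given as not passing. For DSS_AcBb minus Healthy the number was 5 in each direction. Up to 4 members of each function list with the smallest p were added. Genes named outside the rule are marked as chosen after their values were seen. A few genes that the rule took are not reported here.

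Gene lists were also fixed before the data were examined. The 22 function lists were goblet cell and mucus, mature absorptive colonocyte, crypt stem cell, fetal-like regenerative epithelium, enteroendocrine cell, tuft cell, antimicrobial defence, interferon response, MHC class II presentation, MHC class I presentation, cytokines and chemokines, tight and adherens junctions, short-chain fatty acid uptake and fatty acid oxidation, oxidative phosphorylation, cell cycle, unfolded protein response, cholesterol synthesis, xenobiotic and oxidative defence, glycolysis and hypoxia, ion and water transport, wound repair and matrix remodelling, and lytic cell death. The 17 check lists held markers of pan-epithelial, pan-leukocyte, T cell and innate lymphoid, B cell and plasma cell, macrophage and dendritic cell, neutrophil, fibroblast, endothelial, smooth muscle, enteric glia and neuron, squamous epithelium, small intestine, distal position Hox, dissociation stress, mitochondrially encoded, ribosomal protein and erythrocyte genes. Each list with at least 5 tested members was tested with camera (limma 3.58.1), which compares the list with all other genes, at its preset correlation between genes of 0.01. P values were adjusted over the function lists, and separately over the check lists. The same test with a correlation estimated from the data, and fry, which asks whether the members of a list move on balance in 1 direction, were run beside it. For every list the members called over all genes were counted, and those called with p values adjusted over the list alone.

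For the genes changed by DSS, their values in DSS_AcBb minus DSS were set beside 20 simulated data sets with no effect. Both contrasts share the DSS libraries, so chance alone makes their fold changes oppose each other. With 3 DSS libraries, they could not be split into 2 sets of at least 2 libraries each. The overlap of lists with the genes called in opposite directions was tested with a 1-sided Fisher's exact test over 44 tests, among the genes called in the same direction in DSS minus Healthy without Healthy 2. The same test among all 15413 genes was set aside, because every gene called in opposite directions is a gene called in DSS. In 20 further simulations both effects kept their fitted size and that of the bacteria was shuffled among genes of similar level, within 20 bins of expression. These carry the estimation error of the fitted effects as if it were real, so they call more genes than the data. The new noise added to it also weakens their correlation and their share of opposite signs. The overlap tests and the shuffled simulations were added after the data were examined. So were the test of the mitochondrial share and the rules that leave leukocytes and stromal cells open as explanations, which replaced tests whose outcome had been seen. Genes of a list are correlated, so its p values describe these libraries only.

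The scripts were tested on simulated counts drawn from the real means and library sizes. For DSS minus Healthy, with 15223 genes simulated, 52.5% of the genes changed by 1 on the log2 scale and 88.0% of those changed by 2 were recovered, and 6.17% of the calls were false. For DSS_AcBb minus DSS the shares recovered were 66.3% and 93.0%, and 8.67% of the calls were false. Without the library Healthy 2, the shares recovered were 74.0% and 95.9% for DSS minus Healthy and 79.0% and 99.0% for DSS_AcBb minus DSS, over 15337 genes. Simulated genes vary independently, and no simulated library stands apart from its group as Healthy 2 does. These shares therefore test the scripts and do not give the power or the false calls in the real data.

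The alternatives planned before the data were examined were DESeq2 size factors and upper-quartile scaling in place of TMM, no filter, a filter of at least 10 reads in at least 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom with library quality weights, a fit to the 2 compared groups only, the replicate number as a block, a minimum absolute log2 fold change of 1, an adjusted p under 0.01, and leaving out each library of the compared groups in turn. Removing the mitochondrially encoded genes, and leaving out Healthy 2 for DSS_AcBb minus DSS, were added after seeing the data.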

Results

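RNA was sequenced from colonic epithelial cells of 3 Healthy, 3 DSS and 3 DSS_AcBb mice, 9 libraries in all. Healthy mice had no colitis, DSS mice had colitis induced with dextran sodium sulfate, and DSS_AcBb mice had received Anaerostipes caccae and Bifidobacterium bifidum before it. Counted reads per library were 59262263, 46592600 and 52375621 in Healthy 1 to 3. They were 54445629, 59958077 and 45254184 in DSS 1 to 3, and 43877370, 58444543 and 62696344 in DSS_AcBb 1 to 3. Mitochondrially encoded mRNAs took 27.2% to 48.5% of the reads in 8 libraries and 9.23% in Healthy 2 (Wilson 95% interval 9.222% to 9.239%). Healthy 2 also stood apart on the first principal component of the tested genes. Its score was -86.9 on a component that held 46.9% of the variance, while the other 8 lay between -3.29 and 26.1. Clca1, Fcgbp and Mptx1 were high in it, at 2115, 3184 and 1964 CPM. The same genes were at 73.35, 238.7 and 184.8 CPM in Healthy 1 and at 82.93, 259.1 and 188.2 CPM in Healthy 3. Muc2 and Reg3b, like these chosen after their values were seen, were low in it, at 4828 and 121.5 CPM, against 7492 and 2063 CPM in Healthy 1 and 8193 and 1988 CPM in Healthy 3. Its level of H2-Ab1, a chain of an MHC class II molecule, was 3.958 CPM, against 20.55 and 20.3 CPM. Results without Healthy 2 therefore stand beside each comparison. For DSS_AcBb minus DSS this alternative was chosen after seeing the data. It takes the spread of Healthy from Healthy 1 and 3 alone, whose read counts were close (Spearman correlation 0.997, against 0.972 and 0.973 with Healthy 2). DSS 2 and 3 were close as well, as were DSS_AcBb 2 and 3 (both 0.997). More calls without Healthy 2 may therefore rest on a smaller spread between mice in that fit.

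**Figure D1:**
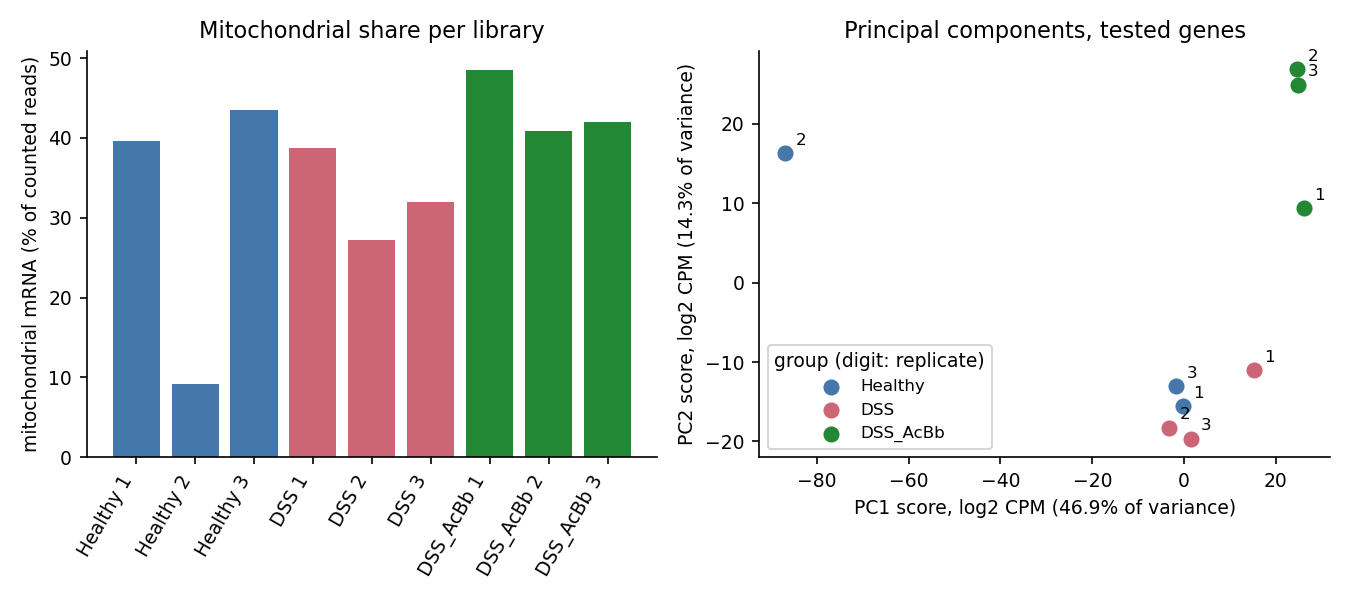
Left, the share of counted reads on mitochondrially encoded mRNAs in each library (bars, in percent). Right, scores of the 9 libraries on the first 2 principal components of log2 CPM, where Healthy 2 lies at -86.9 on the first component and the other 8 between -3.29 and 26.1.

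Epithelial markers were abundant in every group. Epcam, the surface protein used to isolate the cells, was at 965 ± 89.1 CPM in Healthy, 989 ± 19 in DSS and 871 ± 18.9 in DSS_AcBb (SD, n = 3 per group). None of the 12 pan-epithelial genes was called in any comparison with all 9 libraries. Without Healthy 2 Elf3 was called lower for DSS minus Healthy, Tspan8 for DSS_AcBb minus DSS, and Elf3, Vil1 and Cldn7 for DSS_AcBb minus Healthy. As a list they were lower in DSS_AcBb than in DSS (none adjusted over the list alone, median -0.15, camera adjusted p = 0.0232, adjusted p = 0.237 with an estimated correlation) and than in Healthy (5 lower adjusted over the list alone, median -0.22, camera adjusted p = 0.00953, adjusted p = 0.468 with an estimated correlation). For DSS minus Healthy the camera adjusted p was 0.455, with none adjusted over the list alone. Markers of other cell types were largely not analysed here. Tested were 2 of 10 pan-leukocyte, 2 of 14 T cell and innate lymphoid, 0 of 12 B cell and plasma cell, 4 of 15 macrophage and dendritic cell and 1 of 11 neutrophil genes. The others were 3 of 12 fibroblast, 4 of 10 endothelial, 2 of 10 smooth muscle and 4 of 9 enteric glia and neuron genes. These lists were too short for a list test. Their 1 member called with all 9 libraries was C1qa, a complement component made by macrophages, in DSS minus Healthy. This gene, and the others named from these lists and the pan-epithelial one, were chosen after their values were seen. It stood at 0.645 ± 0.335 CPM in Healthy, 3.28 ± 0.415 in DSS and 0.874 ± 0.0699 in DSS_AcBb, a log2 change of 2.36 for DSS minus Healthy (adjusted p = 0.0354). Adjusted over the list alone, 1 macrophage and dendritic cell gene was higher in DSS than in Healthy and 1 lower in DSS_AcBb than in DSS. In the same adjustment 1 enteric glia and neuron gene was higher in each comparison. The fibroblast list had 1 gene higher and 1 lower in DSS_AcBb than in either other group, adjusted over the list alone, and 1 smooth muscle gene was lower in DSS_AcBb than in Healthy. Without Healthy 2 more of them were called over all genes. For DSS_AcBb minus DSS C1qa (-1.91, adjusted p = 0.00463) and the fibroblast gene Pdgfrb were lower, and the fibroblast genes Col1a1 and Fbln1 and the neuronal gene Elavl4 were higher. Fbln1 was lower and C1qa higher for DSS minus Healthy, and Col1a1 was higher and Mylk, of smooth muscle, lower for DSS_AcBb minus Healthy.

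Haemoglobin genes, which mark red blood cells, were higher in DSS_AcBb. All 4 erythrocyte genes tested were called for DSS_AcBb minus Healthy (median log2 change 4.69). None was called for DSS minus Healthy (median 2.52) or DSS_AcBb minus DSS (median 2.17), and all 4 were higher in both when adjusted over the list alone. Without Healthy 2, 3 of the 4 were called for DSS_AcBb minus DSS. Posterior Hox genes, which mark distal positions of the gut, were lower as a list in DSS than in Healthy. Of 5 genes 4 had negative values, none was called, and 3 were lower when adjusted over the list alone (median -0.84, camera adjusted p = 0.000333, adjusted p = 0.388 with an estimated correlation). They were higher in DSS_AcBb than in DSS, where again none was called and 2 were higher when adjusted over the list alone (median 0.71, camera adjusted p = 1.68e-08, adjusted p = 0.081 with an estimated correlation). Without Healthy 2 Hoxb13, Hoxd11 and Hoxd13, chosen after their values were seen, were called there and all 5 were higher when adjusted over the list alone, while the adjusted p with an estimated correlation was 0.189. For DSS_AcBb minus Healthy the camera adjusted p was 0.152 (median 0.70), and without Healthy 2 they were higher in DSS_AcBb (adjusted p = 0.00706, lost at 0.586 with an estimated correlation). The median for DSS minus Healthy was -0.32 without Healthy 2. Hoxb13 was highest in Healthy 2, at 180 CPM, against 72.79 and 76.7 CPM in Healthy 1 and 3.

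**Figure D2:**
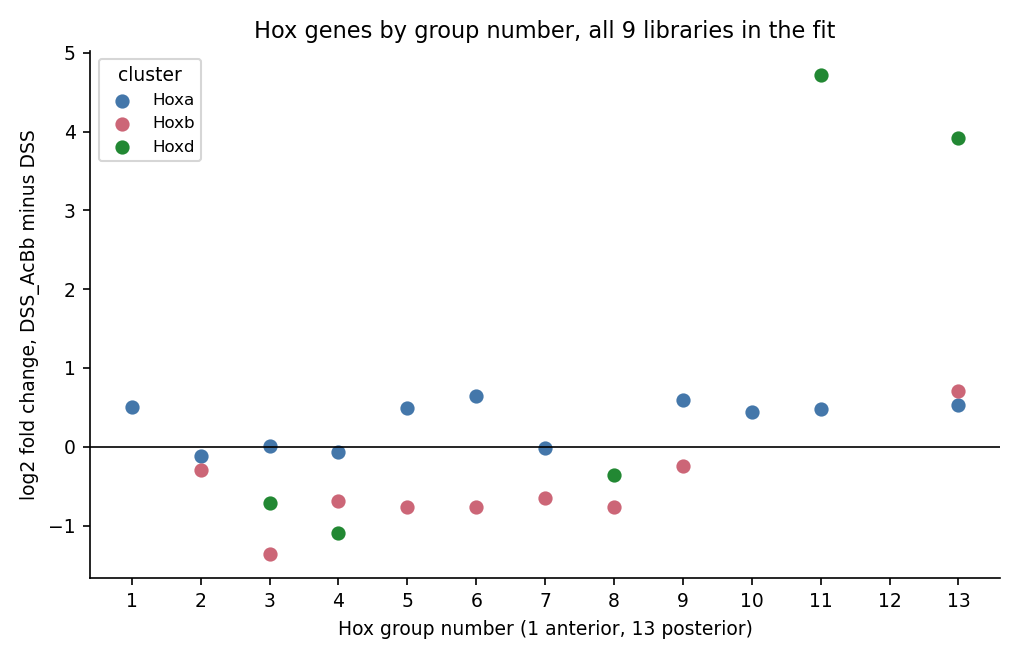
Log2 fold change of each tested Hox gene in DSS_AcBb minus DSS against its group number in the cluster, from anterior (1) to posterior (13), coloured by cluster. The 6 genes of groups 10 to 13 had a median of 0.62 and the 17 genes of groups 1 to 8 a median of -0.36.

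Mitochondrially encoded genes were higher in DSS_AcBb than in DSS (13 genes, median 0.62, camera adjusted p = 0.0232, adjusted p = 0.707 with an estimated correlation) and than in Healthy (median 0.58, camera adjusted p = 0.0112, adjusted p = 0.612 with an estimated correlation), with none called over all genes or adjusted over the list alone. Without Healthy 2 the second call was lost (adjusted p = 0.716). For DSS minus Healthy their camera adjusted p was 0.522, and without Healthy 2 they were lower in DSS (median -0.51, adjusted p = 0.000193, lost at 0.662 with an estimated correlation, with none of 13 called or adjusted over the list alone). Ribosomal protein genes were higher in DSS (22 genes, none adjusted over the list alone, median 0.19, camera adjusted p = 5.46e-05, adjusted p = 0.691 with an estimated correlation) and in DSS_AcBb (11 higher adjusted over the list alone, median 0.23, camera adjusted p = 5.05e-05, adjusted p = 0.597 with an estimated correlation) than in Healthy. Between the colitis groups their camera adjusted p was 0.371. None was called over all genes, against 1 higher in DSS and 3 in DSS_AcBb than in Healthy without Healthy 2. The small intestine list was called for DSS_AcBb minus DSS, where the test pointed up (mean 0.40, median -0.24, camera adjusted p = 0.0232, adjusted p = 0.152 with an estimated correlation). Of its 7 genes 4 had negative values, while Lyz1 was called and 2 were higher adjusted over the list alone. Without Healthy 2 the list was not called (adjusted p = 0.121), with 2 genes higher and 1 lower. For DSS minus Healthy and DSS_AcBb minus Healthy its camera adjusted p was 0.522 and 0.413, with 3 lower and 1 higher adjusted over the list alone in the second. The squamous epithelium list had camera adjusted p of 0.987, 0.597 and 0.766 for DSS minus Healthy, DSS_AcBb minus DSS and DSS_AcBb minus Healthy, with 2 lower adjusted over the list alone in the last. The dissociation stress list had 0.987, 0.597 and 0.72, with 2 lower adjusted over the list alone for DSS minus Healthy, and 1 called lower and 3 lower adjusted over the list alone for DSS_AcBb minus Healthy. Without Healthy 2, 1 of its genes was called higher and 2 lower in the first comparison, and 2 lower in each of the others. Median, mean and test differed in sign for squamous epithelium and mitochondrially encoded genes in DSS minus Healthy, for squamous epithelium and small intestine in DSS_AcBb minus Healthy, and for dissociation stress in all 3 comparisons.

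The comparison of DSS with Healthy addressed what colitis changes in the epithelium. In DSS, 14 of 24 genes of the interferon response and 4 of 14 of MHC class I presentation fell. As lists, genes of MHC class II presentation and of mature absorptive colonocytes were lower and enteroendocrine genes higher, with 0 of 8, 3 of 17 and 2 of 14 called. These 3 list calls were lost with an estimated correlation (adjusted p = 0.0582, 0.29 and 0.232). Without Healthy 2 the MHC class II list passed with it (adjusted p = 0.00988), and the other two did not (0.414 and 0.312). Zbp1, an interferon-induced sensor of nucleic acids (gene ID 58203, chromosome 2, 173206612 to 173218959 in GRCm38), went from 23.2 ± 3.13 CPM in Healthy to 5.97 ± 0.566 in DSS (SD, n = 3 per group), a log2 change of -1.96 (SE 0.127, adjusted p = 0.00105). Tap1, a subunit of the peptide transporter that loads MHC class I (gene ID 21354, chromosome 17, 34187556 to 34197225), went from 34.2 ± 5.61 to 12.6 ± 1.12 CPM (log2 change -1.44, SE 0.133, adjusted p = 0.0056). Pyy, the gut hormone peptide YY (gene ID 217212, chromosome 11, 102106676 to 102107832), went from 19.8 ± 6.75 to 61.1 ± 11.2 CPM (log2 change 1.63, SE 0.251, adjusted p = 0.031). The edgeR test called 92 of 15301 genes, 24 higher and 68 lower in DSS, and 1906 had an unadjusted p under 0.05. Without Healthy 2 it called 534, 254 higher and 280 lower, among them all 92 in the same direction. Leaving out DSS 2 or DSS 3 left 3 calls each, and leaving out Healthy 1, Healthy 3 or DSS 1 gave 55, 31 and 44. The 3 were Zbp1 and, chosen after their values were seen, Krt36, a keratin (-2.13, adjusted p = 0.00229), and Upp1, a uridine phosphorylase (-1.93, adjusted p = 0.00229).

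**Figure D3:**
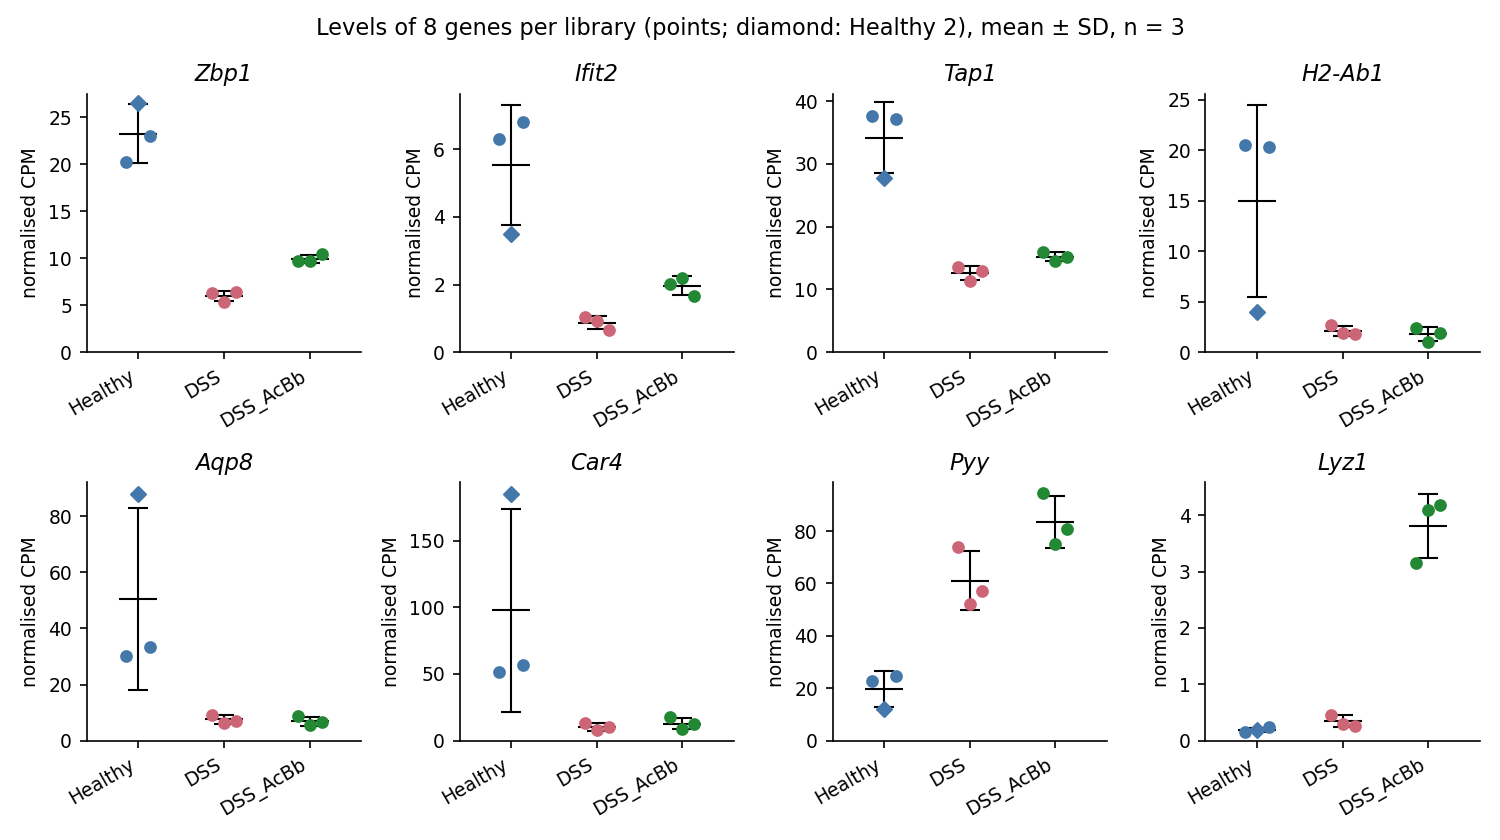
Normalised CPM of 8 genes in each library (points, with Healthy 2 as a diamond) with the mean and SD of the 3 libraries of each group. Zbp1 had a mean of 23.2 CPM in Healthy, 5.97 in DSS and 9.91 in DSS_AcBb, and Lyz1 a mean of 0.19, 0.342 and 3.81 CPM.

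Of the 24 interferon genes 14 fell, and 21 were lower and 1 higher when adjusted over the list alone (median -1.76, camera adjusted p = 1.1e-54, adjusted p = 0.00021 with an estimated correlation). Ifit2, which binds viral RNA, fell from 5.54 ± 1.78 to 0.871 ± 0.195 CPM. Stat2, a transcription factor of interferon signalling, had a log2 change of -0.82. Among the 10 lower genes of largest change were Oas3 (-4.40) and Oasl2 (-2.91), of the oligoadenylate synthetase family, Ifit1bl1 (-2.53) and Ifit1 (-2.27), relatives of Ifit2, and Gbp3 (-2.38), a guanylate-binding protein. Without Healthy 2, 21 of the 24 fell, and the changes of Oas3, Oasl2, Ifit1 and Gbp3 were smaller, at -3.35, -2.28, -1.92 and -2.06. In MHC class I presentation 4 of 14 genes fell, 11 adjusted over the list alone (median -0.67, camera adjusted p = 3.46e-24, adjusted p = 0.0138 with an estimated correlation). They were Tap1 and the immunoproteasome subunits Psmb8 (-1.73), Psmb9 (-1.44) and Psmb10 (-0.64), and 11 of the 14 fell without Healthy 2. In MHC class II presentation none of 8 genes was called over all genes, and 6 were lower when adjusted over the list alone (median -1.91, camera adjusted p = 1.06e-06, adjusted p = 0.0582 with an estimated correlation). H2-Ab1 and Cd74, the chaperone of class II molecules, were at 14.9 ± 9.51 and 59 ± 45.6 CPM in Healthy and at 2.1 ± 0.48 and 8.87 ± 0.856 in DSS. Healthy 2 held them at 3.958 and 6.415 CPM, near the DSS level. Without it 6 of the 8 fell, with log2 changes of -3.28 for H2-Ab1 and -3.26 for Cd74.

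Of 17 mature absorptive colonocyte genes 3 fell, and 9 were lower and 1 higher when adjusted over the list alone (median -0.91, camera adjusted p = 2.53e-09, adjusted p = 0.29 with an estimated correlation). Without Healthy 2 the median was -0.17, with 7 of 17 values positive and 5 called lower. The 3 with all libraries were Aqp8, a water channel (-2.75), Car4, a carbonic anhydrase (-3.23, gene ID 12351, chromosome 11, 84957754 to 84966054), and Tmigd1, an epithelial adhesion protein (-1.36). Healthy 2 raised the Healthy mean of Aqp8 and Car4, at 88.12 and 185.1 CPM. They were at 30.03 and 51.13 CPM in Healthy 1 and at 33.38 and 56.57 CPM in Healthy 3. Krt20, a keratin of differentiated cells, was 280 ± 7.35 CPM in Healthy and 130 ± 17.1 in DSS (adjusted p = 0.0621). In ion and water transport Aqp8 fell and Aqp1, another water channel, rose by 0.73, and of 20 genes 4 were lower and 2 higher when adjusted over the list alone (median -0.42, camera adjusted p = 0.0293, adjusted p = 0.51 with an estimated correlation). Without Healthy 2 the median of that list was 0.11 and its call was lost (adjusted p = 0.214). Cholesterol synthesis had none of 20 genes called over all genes, but all had negative values and 18 were lower when adjusted over the list alone (median -0.39, camera adjusted p = 2.25e-16, adjusted p = 0.023 with an estimated correlation). Without Healthy 2, 11 of the 20 fell, but the list no longer passed with an estimated correlation (adjusted p = 0.051). Among its members were the pathway enzymes Sqle (-0.48), Mvk (-0.48) and Mvd (-0.54). Mptx1, a pentraxin of the gut (gene ID 66289, chromosome 1, 174330518 to 174332877), fell most among the genes of largest change, -5.73 (SE 1.01, adjusted p = 0.0485) and -3.67 without Healthy 2. Pla2g4c, a phospholipase, had a log2 change of -2.30.

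All 14 enteroendocrine genes had positive values with all 9 libraries, and 10 without Healthy 2, where the median was 0.63 and 6 were called higher. Healthy 2 held Neurod1, Rfx6 and Insm1 at 0.8341, 0.6824 and 1.183 CPM, against 6.614, 7.43 and 12.5 CPM in Healthy 1. Pyy and Sct, which encodes secretin, rose (1.63 and 1.29), and 7 were higher when adjusted over the list alone (median 1.04, camera adjusted p = 5.34e-13, adjusted p = 0.232 with an estimated correlation). Insl5, a hormone of colonic endocrine cells, was 15.6 ± 3.18 CPM in Healthy and 35 ± 7.85 in DSS (adjusted p = 0.0631). Other genes of large change that rose were Cmah, which hydroxylates sialic acid (1.71), Rian, an imprinted non-coding RNA (1.32), and Acot2, an acyl-CoA thioesterase (1.20). They also included Mboat2, a lysophospholipid acyltransferase (1.18), B3galt2, a galactosyltransferase (1.11), Vav3, a guanine nucleotide exchange factor (1.08), Gsta4, a glutathione transferase (0.95), and Pmaip1, the proapoptotic protein Noxa (0.94). Summed haemoglobin genes had the same direction, at 1.15 to 1.98 CPM in the Healthy libraries and 3.66 to 17.9 CPM in the DSS libraries.

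The other lists called had no member called over all genes. Higher in DSS were fetal-like regenerative epithelium (16 genes, 1 lower and 2 higher adjusted over the list alone, median 0.38, camera adjusted p = 0.003, adjusted p = 0.29 with an estimated correlation) and wound repair and matrix remodelling (15 genes, none adjusted over the list alone, median 0.31, camera adjusted p = 0.0422, adjusted p = 0.42 with an estimated correlation). In the first, Clu, which encodes clusterin, was 11.2 ± 6.75 CPM in Healthy and 45.9 ± 10.4 in DSS (adjusted p = 0.0977). Lower in DSS were cell cycle (23 genes, 1 lower adjusted over the list alone, median -0.58, camera adjusted p = 3.13e-08, adjusted p = 0.42 with an estimated correlation) and oxidative phosphorylation (26 genes, none adjusted over the list alone, median -0.18, camera adjusted p = 3.66e-05, adjusted p = 0.468 with an estimated correlation). Top2a, a topoisomerase of dividing cells, was 46.6 ± 1.09 CPM in Healthy and 23.2 ± 7.33 in DSS (adjusted p = 0.104). Also lower were crypt stem cell (15 genes, 1 lower adjusted over the list alone, median -0.31, camera adjusted p = 0.0399, adjusted p = 0.42 with an estimated correlation) and glycolysis and hypoxia (20 genes, 2 lower adjusted over the list alone, median -0.13, camera adjusted p = 0.0414, adjusted p = 0.29 with an estimated correlation). Axin2, a target of Wnt signalling, was 21.1 ± 4.76 and 11 ± 1.77 CPM (adjusted p = 0.0656), and Pkm, a pyruvate kinase, 535 ± 110 and 341 ± 9.83 CPM (adjusted p = 0.0728). The medians of crypt stem cell and oxidative phosphorylation were -0.17 and -0.12 without Healthy 2. Single libraries ended some of these calls: crypt stem cell without Healthy 3, Healthy 1 or DSS 1 (adjusted p = 0.09 to 0.257), glycolysis and hypoxia without Healthy 2, DSS 3, Healthy 3 or DSS 2 (adjusted p = 0.0531 to 0.128) and wound repair and matrix remodelling without Healthy 3, Healthy 1, Healthy 2 or DSS 1 (adjusted p = 0.09 to 0.294). In ion and water transport the call was also lost without DSS 1 (adjusted p = 0.11). Other calls were kept with medians over 1.5 times smaller. Without DSS 1 these were -0.35 for cell cycle, -0.12 for oxidative phosphorylation and 0.25 for fetal-like regenerative epithelium.

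Not called were goblet cell and mucus (camera adjusted p = 0.564, 1 lower adjusted over the list alone), tuft cell (0.593), antimicrobial defence (0.591, 3 lower and 3 higher adjusted over the list alone), cytokines and chemokines (0.0801, 1 lower and 1 higher adjusted over the list alone) and tight and adherens junctions (0.727). Only 6 of 14 tuft cell and 13 of 22 cytokine and chemokine genes were tested. Members silent in any library are missing, so a cytokine turned on by colitis alone would not be seen. Neither were short-chain fatty acid uptake and fatty acid oxidation (0.237), unfolded protein response (0.113, 1 lower adjusted over the list alone), xenobiotic and oxidative defence (0.124, 1 higher adjusted over the list alone) and lytic cell death (0.983, 1 lower adjusted over the list alone). Median, mean and test differed in sign for goblet cell and mucus, tuft cell, tight and adherens junctions and lytic cell death. Tnfsf10, the death ligand TRAIL of the cytokine list, had a log2 change of -1.11 and was called. Reg4, a lectin of the antimicrobial list, was 98.1 ± 72 CPM in Healthy and 434 ± 48.3 in DSS (adjusted p = 0.07), and rose by 2.94 without Healthy 2. Without Healthy 2, 4 further lists were called, and none of the 4 with an estimated correlation (adjusted p = 0.051 to 0.414). Antimicrobial defence (adjusted p = 4.39e-05) and the unfolded protein response (0.000135) were lower. Fatty acid oxidation (0.000603) and xenobiotic and oxidative defence (0.034) were higher.

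The comparison of DSS_AcBb with DSS addressed what the bacteria change in the colitic epithelium. Lyz1, the lysozyme of Paneth cells (gene ID 17110, chromosome 10, 117287795 to 117292868), rose from 0.342 ± 0.103 CPM in DSS to 3.81 ± 0.57 in DSS_AcBb (SD, n = 3 per group), a log2 change of 3.48 (SE 0.271, adjusted p = 0.00537). Genes of the interferon response and of enteroendocrine cells were higher as lists in DSS_AcBb. Genes of fatty acid oxidation, of xenobiotic defence and of lytic cell death were lower as lists. All 5 of these list calls were lost with an estimated correlation (adjusted p = 0.053 to 0.452), as were all others between the colitis groups. Splits mixing the 2 groups called up to 12 lists, against 15 for the real split. Fry does not compare a list with other genes. With it, interferon response, xenobiotic defence and lytic cell death passed (adjusted p = 0.0162, 0.0332 and 0.0162). With all 9 libraries Lyz1 was the 1 gene called by edgeR and none was called lower, while 1815 had an unadjusted p under 0.05, and DESeq2 called 347 and limma-voom 6731. Lyz1 lies under 5 CPM and was chosen after its values were seen, and its call was lost without DSS 2, DSS 3, DSS_AcBb 2 or DSS_AcBb 3 (adjusted p = 0.0622 to 0.104). It was also lost with the planned replicate block, which called no gene here (adjusted p = 0.103 for Lyz1).

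Of 24 interferon genes none was called over all genes, 21 had positive values and 9 were higher when adjusted over the list alone (median 0.45, camera adjusted p = 4.39e-09, adjusted p = 0.053 with an estimated correlation). Zbp1 was 5.97 ± 0.566 CPM in DSS and 9.91 ± 0.432 in DSS_AcBb (log2 change 0.73, adjusted p = 0.13), and Ifit2 0.871 ± 0.195 and 1.97 ± 0.273 CPM (1.17, adjusted p = 0.222). Oasl2 was 5.47 ± 1.26 and 14.4 ± 2 CPM (1.39, adjusted p = 0.244). Of 14 enteroendocrine genes 13 had positive values, with none called over all genes or adjusted over the list alone (median 0.57, camera adjusted p = 0.000613, adjusted p = 0.452 with an estimated correlation). Neurod1, Rfx6 and Insm1, transcription factors of enteroendocrine cells, were 6.22 ± 1.71, 5.72 ± 1.92 and 8.95 ± 2.93 CPM in DSS. In DSS_AcBb they were 14.9 ± 0.404, 14.8 ± 0.735 and 22.2 ± 1.01 CPM. Also higher, with no member called over all genes, were unfolded protein response (20 genes, none adjusted over the list alone, median 0.32, camera adjusted p = 0.00973, adjusted p = 0.64 with an estimated correlation), cell cycle (23 genes, none adjusted over the list alone, median 0.23, camera adjusted p = 0.0062, adjusted p = 0.64 with an estimated correlation) and glycolysis and hypoxia (20 genes, none adjusted over the list alone, median 0.09, camera adjusted p = 0.0454, adjusted p = 0.32 with an estimated correlation). Single libraries ended these calls: unfolded protein response without DSS 2 (adjusted p = 0.0755), cell cycle without DSS_AcBb 2 or DSS 1 (adjusted p = 0.172 to 0.882) and glycolysis and hypoxia without DSS 3, DSS 2 or DSS_AcBb 1 (adjusted p = 0.0946 to 0.303).

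All 25 genes of short-chain fatty acid uptake and fatty acid oxidation had negative values, with none called over all genes or adjusted over the list alone (median -0.39, camera adjusted p = 4.97e-09, adjusted p = 0.296 with an estimated correlation). In xenobiotic and oxidative defence 16 of 17 values were negative, none was called and 2 were lower when adjusted over the list alone (median -0.25, camera adjusted p = 9.93e-06, adjusted p = 0.0608 with an estimated correlation). Gsta4 was 38.5 ± 7.49 CPM in DSS and 17.1 ± 1.63 in DSS_AcBb (-1.17, adjusted p = 0.119), beside 19.9 ± 1.98 in Healthy. In lytic cell death 14 of 18 values were negative, none was called and 2 were lower when adjusted over the list alone (median -0.22, camera adjusted p = 3.46e-05, adjusted p = 0.0608 with an estimated correlation). Its members Gsdmc2 (gene ID 331063, chromosome 15, 63824328 to 63845193) and Gsdmc3, pore-forming gasdermins, were 633 ± 129 and 300 ± 64.3 CPM in DSS and 323 ± 10 and 152 ± 5.22 in DSS_AcBb (both adjusted p = 0.188). Summed haemoglobin genes had the other direction, at 3.66 to 17.9 CPM in the DSS libraries and 37.7 to 43.0 CPM in the DSS_AcBb libraries.

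Further lists were lower with no member called over all genes. They were tight and adherens junctions (20 genes, 2 lower adjusted over the list alone, median -0.16, camera adjusted p = 0.00076, adjusted p = 0.32 with an estimated correlation), ion and water transport (20 genes, 1 lower adjusted over the list alone, median -0.23, camera adjusted p = 0.00109, adjusted p = 0.399 with an estimated correlation) and mature absorptive colonocyte (17 genes, none adjusted over the list alone, median -0.60, camera adjusted p = 0.00124, adjusted p = 0.452 with an estimated correlation). Cftr, the chloride channel of the transport list, was 112 ± 24.4 CPM in DSS and 64.1 ± 3.08 in DSS_AcBb (adjusted p = 0.287). Lower too were wound repair and matrix remodelling (15 genes, none adjusted over the list alone, median -0.24, camera adjusted p = 0.00573, adjusted p = 0.32 with an estimated correlation) and cytokines and chemokines (13 genes, 1 lower adjusted over the list alone, median -0.26, camera adjusted p = 0.0224, adjusted p = 0.399 with an estimated correlation). Hbegf, a growth factor of the EGF family, was 407 ± 13.5 and 289 ± 30.9 CPM (adjusted p = 0.282). The last were antimicrobial defence (16 genes, 2 lower adjusted over the list alone, median -0.25, camera adjusted p = 0.0231, adjusted p = 0.21 with an estimated correlation) and fetal-like regenerative epithelium (16 genes, none adjusted over the list alone, median -0.27, camera adjusted p = 0.046, adjusted p = 0.452 with an estimated correlation). Reg4 was 434 ± 48.3 and 179 ± 39.1 CPM (adjusted p = 0.293). Calls that depended on single libraries were wound repair and matrix remodelling without DSS 1 (adjusted p = 0.159), cytokines and chemokines without DSS 1 (adjusted p = 0.0574), antimicrobial defence without DSS_AcBb 1 or DSS 1 (adjusted p = 0.0537 to 0.092) and fetal-like regenerative epithelium without DSS_AcBb 3, DSS_AcBb 2 or DSS 1 (adjusted p = 0.0811 to 0.414). Medians over 1.5 times smaller, with the call kept, were those of absorptive colonocytes (-0.36), cytokines and chemokines (-0.16) and wound repair (-0.14) without DSS_AcBb 2, and of tight and adherens junctions (-0.11) without DSS 1. Over 1.5 times larger in size were those of wound repair (-0.39) and cell cycle (0.44) without DSS 2. The same held for cell cycle (0.42) without DSS_AcBb 1 and for glycolysis and hypoxia (0.13) without DSS_AcBb 2. Not called were goblet cell and mucus (camera adjusted p = 0.706), crypt stem cell (0.684), tuft cell (0.329, 1 lower adjusted over the list alone), MHC class II presentation (0.177), MHC class I presentation (0.406), oxidative phosphorylation (0.205) and cholesterol synthesis (0.706). Median, mean and test differed in sign for goblet cell and mucus and for crypt stem cell. Without Healthy 2 MHC class II presentation was lower (adjusted p = 0.0439), a call lost with an estimated correlation (adjusted p = 0.349).

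The rule's minimum of 5 CPM left out Lyz1. Among the genes within the rule's limits on level and name, the 5 with the smallest p in each direction did not pass with all 9 libraries. Positive log2 changes were those of Hspa4l, a heat shock protein (0.72), Dmpk, a kinase (1.27), Hoxd13 (3.92), Upp1 (1.10) and Dll1, a Notch ligand (0.69), with adjusted p of 0.119 to 0.127. Negative ones were those of Gsta4 (-1.17), Cyp2w1, a cytochrome P450 (-1.69), Vav3 (-1.03), Acacb, an acetyl-CoA carboxylase (-1.16), and Dmbt1, a mucosal scavenger protein (-1.06), with adjusted p of 0.119 to 0.13. Hoxd13 lay at 7.694, 24.58 and 18.38 CPM in DSS_AcBb 1 to 3. Upp1 lies on chromosome 11 (9118008 to 9136170). Healthy 2 belongs to neither group but shares its spread with them in the fit. Without it 1137 genes were called, 560 higher and 577 lower in DSS_AcBb, among them Lyz1 and these 10 in the same directions. The Healthy spread then comes from Healthy 1 and 3 alone, a close pair, so the larger count may rest on a smaller spread. In that fit 11 interferon, 7 enteroendocrine and 6 unfolded protein response genes rose, and 7 genes of lytic cell death, 6 of antimicrobial defence, 5 of fatty acid oxidation and 5 of ion and water transport fell. Other function lists had at most 3 called in 1 direction, and none passed with an estimated correlation (lowest adjusted p = 0.0954). With fry, 10 function lists passed in that fit. Fitting the 6 colitis libraries alone called 553 genes. Leaving out DSS 1 or DSS_AcBb 1 called 8 and 45, and leaving out any other colitis library called 0.

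**Figure D4:**
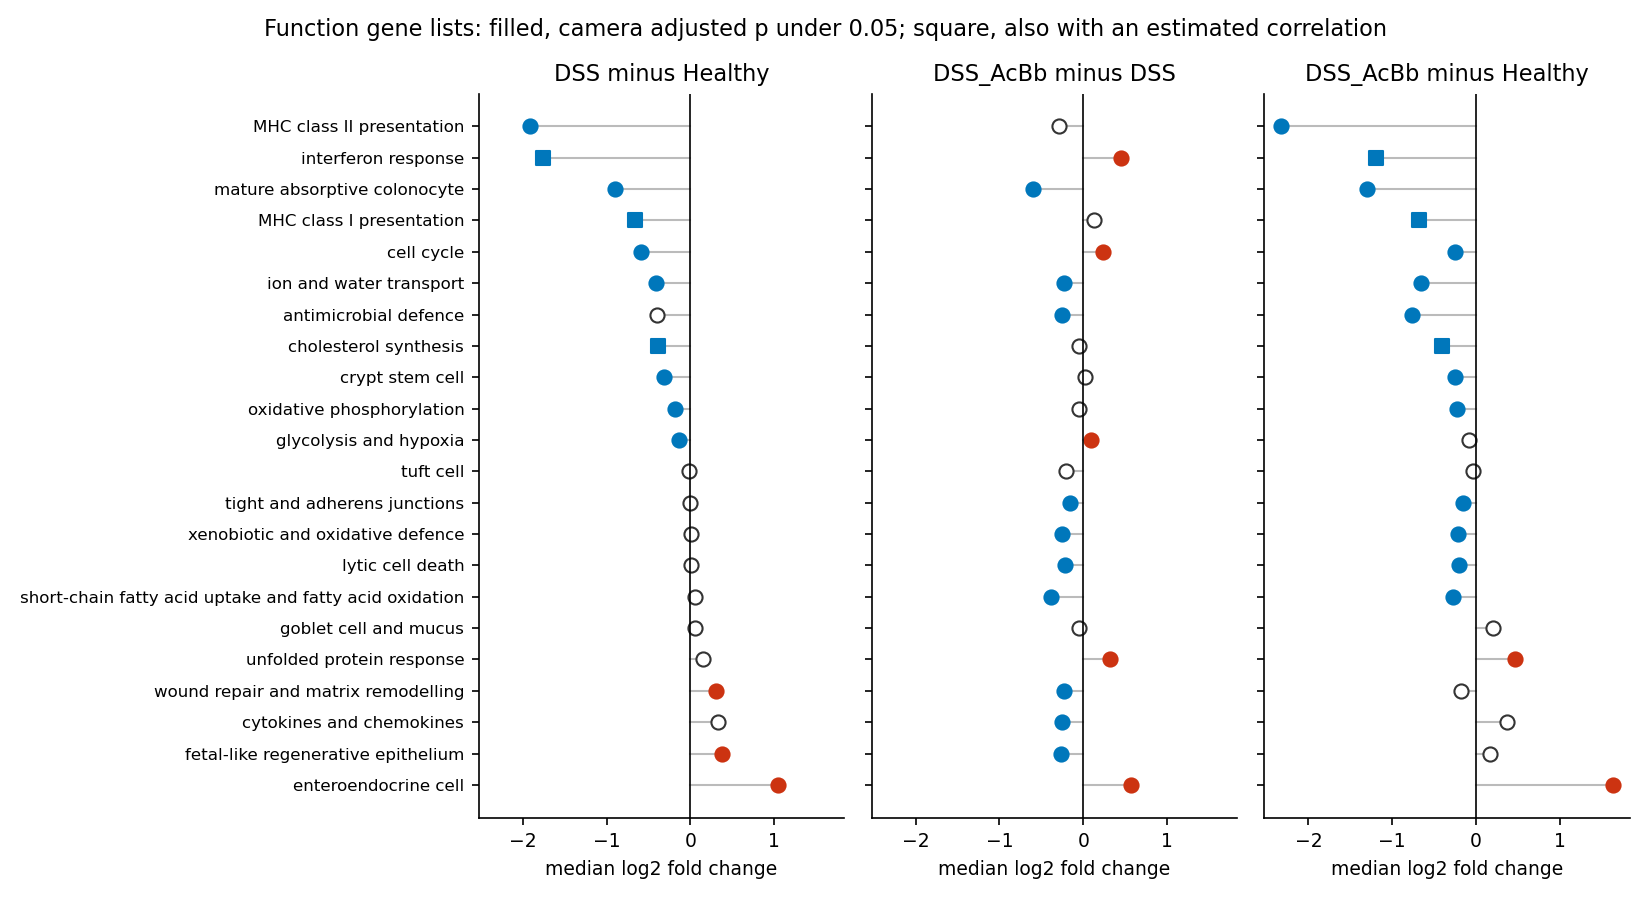
Median log2 fold change of the tested members of the 22 function lists in the 3 comparisons, with lists called higher in red, called lower in blue, and open circles for a camera adjusted p of 0.05 or more. Squares mark lists that also passed with an estimated correlation, which numbered 3 for DSS minus Healthy, 0 for DSS_AcBb minus DSS and 3 for DSS_AcBb minus Healthy.

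Whether genes changed by DSS lay nearer to Healthy in DSS_AcBb was examined next. With all 9 libraries, 80 of the 92 genes changed by DSS had the opposite sign in DSS_AcBb minus DSS. None of them was called there by edgeR, while DESeq2 called 53 genes in opposite directions in both contrasts. The 68 genes that fell in DSS had a median log2 change of -1.50 in DSS minus Healthy and 0.29 in DSS_AcBb minus DSS, which left a median of -1.19 in DSS_AcBb minus Healthy. For the 24 that rose, the median was -0.53 in DSS_AcBb minus DSS and 0.74 in DSS_AcBb minus Healthy. Both contrasts share the DSS libraries, which opposes their fold changes by chance. In 20 simulated data sets with no effect the covariance of the fold changes had a median of -0.0435 (-0.0458 to -0.0394), and the correlation one of -0.498. Both were stronger than in the data, at -0.0336 and -0.201. In 20 further simulations, added after the results were seen, both effects kept their fitted size and that of the bacteria was shuffled among genes of similar level. There the covariance was -0.0412 (-0.0469 to -0.0352) and the correlation -0.161 (-0.185 to -0.141), the first stronger and the second weaker than in the data. A median of 64.1% of the genes changed by DSS had the opposite sign (60.6% to 67.9%), against 87.0% in the data. New noise on effects that already carry estimation error weakens the shuffled correlation and this share, so neither difference shows a return.

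Without Healthy 2, 152 genes were called in opposite directions and 18 in the same direction. The covariance was -0.0568, against -0.0256 in the simulations with no effect (-0.0275 to -0.0238) and -0.0242 in the shuffled ones (-0.0281 to -0.0202). The correlation was -0.361, against -0.112 in the shuffled simulations (-0.126 to -0.0943). Opposite signs made up 62.8% of all genes, against 54.0% (53.6% to 54.7%), and 411 of the 534 genes changed by DSS, against 58.9% (56.2% to 61.0%). These quantities thus exceeded those of the shuffled simulations, while the number of opposite calls did not. New noise on effects that already carry estimation error weakens the shuffled correlation and shares. Of these quantities only the covariance therefore bears on a return. The shuffled simulations gave 165 (156 to 198), above the 152 of the data, with more calls in all, at medians of 1390 for DSS minus Healthy and 2499 for DSS_AcBb minus DSS. Calls in the same direction numbered 89.5 there (77 to 106), against 18 in the data. Among genes called in both contrasts, opposite directions thus outweighed the same direction by more in the data. Estimation error carried as real adds shuffled calls in both directions, so this does not show a return either. In the simulations with no effect the correlation was -0.436 and the share of opposite signs 64.7%, both stronger than in the data. Simulated genes vary independently, so the simulated ranges leave out any deviation that the genes of 1 mouse share. The covariance with all 9 libraries did not exceed the simulated one, but the simulations gave all groups 1 spread per gene. Healthy 2 enters that spread: without it the covariance simulated with no effect went from -0.0435 to -0.0256, with the same DSS libraries. The comparison with all 9 libraries therefore does not decide. For these reasons a return beyond what the shared DSS libraries force was not settled. Leaving out DSS 1 or DSS_AcBb 1 gave 3 opposite calls each, and leaving out any of the other libraries gave 0. Of the 61 genes that were lower in DSS and higher in DSS_AcBb, 11 belonged to the interferon list. All 61 are among the 280 genes lower in DSS, which held 21 interferon genes, so 4.58 were expected (Fisher's exact test, adjusted p = 0.0579, not called). The unfolded protein response held 3 of them and goblet cell and mucus 2, of 4 and 2 lower in DSS (both adjusted p = 0.687). Oasl2 had log2 changes of -2.28 in DSS minus Healthy and 1.39 in DSS_AcBb minus DSS, and Zbp1 of -1.86 and 0.74. No function list passed among the 91 of 254 genes higher in DSS that were lower in DSS_AcBb. The 91 included Reg4 (2.94, then -1.28), Cyp2w1 (1.45, then -1.70) and Gsta4 (1.04, then -1.17).

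**Figure D5:**
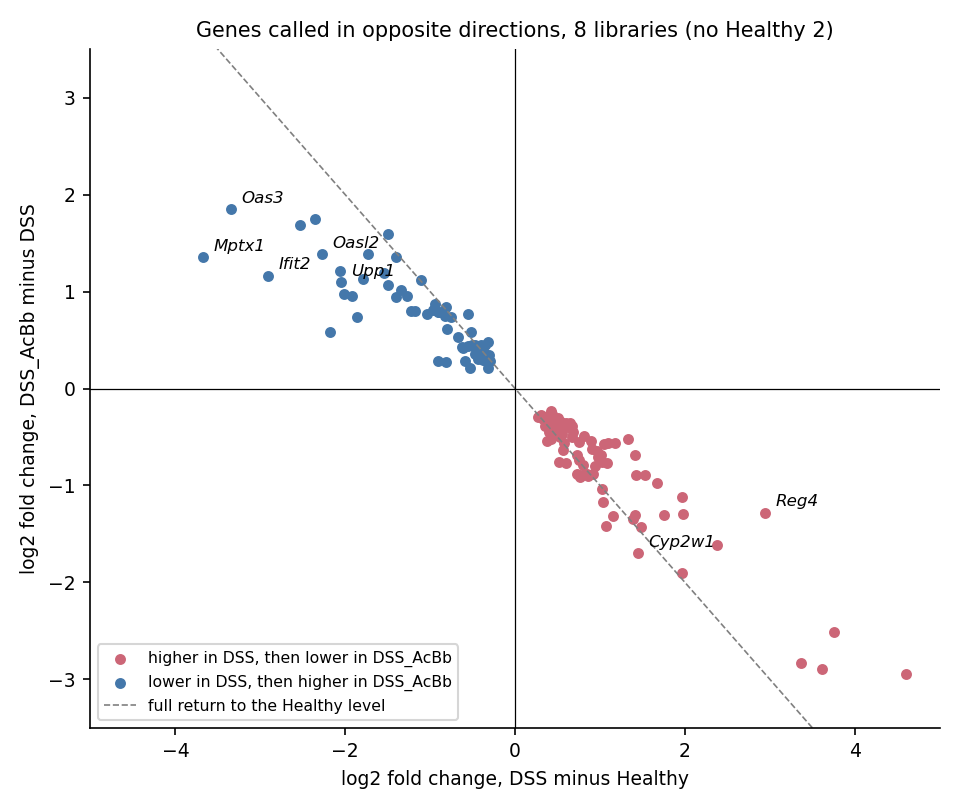
Log2 fold changes in DSS minus Healthy (horizontal) and DSS_AcBb minus DSS (vertical) of the 152 genes called in opposite directions without Healthy 2, 1 point per gene. The dashed line marks a full return to the Healthy level, and 91 genes lie in the lower right and 61 in the upper left.

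The comparison of DSS_AcBb with Healthy addressed how far colitic mice given the bacteria remained from healthy ones. Haemoglobin genes and Hspb1, a small heat shock protein, rose. Hbb-bt went from 0.148 ± 0.068 to 6.22 ± 0.909 CPM (SD, n = 3 per group), and Hbb-bs, Hba-a1 and Hba-a2 had log2 changes of 4.88, 4.49 and 4.43. Hspb1 went from 6.01 ± 3.88 to 68.5 ± 16.2 CPM (log2 change 3.52, SE 0.536, adjusted p = 0.0264). Lower were H2-Ab1 (-3.11), Car4 (-2.94), Aqp8 (-2.87), Slc9a3, a sodium/proton exchanger (-2.68), and Mal, a protein of apical membrane traffic (-2.63). Healthy 2 held Car4, Aqp8 and Slc9a3 above Healthy 1 and 3, and H2-Ab1 and Mal below them. The test called 236 genes, 113 higher and 123 lower, and 3571 had an unadjusted p under 0.05. Without Healthy 2, 930 genes were called, 483 higher and 447 lower, among them all 236 in the same direction. Leaving out Healthy 1, Healthy 3, DSS_AcBb 1, DSS_AcBb 2 or DSS_AcBb 3 gave 8, 6, 117, 4 and 5 calls.

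Interferon genes stayed below Healthy: 6 of 24 fell, and 20 were lower and 1 higher when adjusted over the list alone (median -1.20, camera adjusted p = 6.55e-16, adjusted p = 0.0107 with an estimated correlation). In MHC class I presentation 8 of 14 fell, 10 adjusted over the list alone (median -0.68, camera adjusted p = 5.7e-14, adjusted p = 0.0496 with an estimated correlation). In MHC class II presentation H2-Ab1 and H2-DMa fell, 7 of 8 adjusted over the list alone (median -2.33, camera adjusted p = 9.97e-07, adjusted p = 0.0565 with an estimated correlation). In cholesterol synthesis 7 of 20 fell, 16 adjusted over the list alone (median -0.41, camera adjusted p = 4.37e-12, adjusted p = 0.0496 with an estimated correlation), among them Hmgcs1 (-0.81) and Sqle (-0.59). Of 17 absorptive colonocyte genes Tmigd1, Aqp8, Slc9a3 and Car4 fell, and 14 were lower and 1 higher when adjusted over the list alone (median -1.30, camera adjusted p = 2.79e-13, adjusted p = 0.127 with an estimated correlation). In ion and water transport 3 of 20 fell, 8 adjusted over the list alone (median -0.66, camera adjusted p = 1.02e-05, adjusted p = 0.26 with an estimated correlation), with Aqp4, a water channel, at -1.16. Without Healthy 2 the medians of absorptive colonocytes and of ion and water transport were -0.78 and -0.22, with 8 and 5 genes called lower. Among enteroendocrine genes Pyy (2.08), Insl5 (1.70) and Scg2, a granin (2.19), rose, 11 of 14 adjusted over the list alone (median 1.63, camera adjusted p = 6.06e-17, adjusted p = 0.109 with an estimated correlation). In antimicrobial defence Slpi, a protease inhibitor, rose by 2.28 and Pigr, the transporter of secretory IgA, had a log2 change of -0.59. Of its 16 genes 5 were lower and 1 higher when adjusted over the list alone (median -0.76, camera adjusted p = 0.0307, adjusted p = 0.127 with an estimated correlation), and the list was no longer called without DSS_AcBb 2, DSS_AcBb 1, Healthy 1 or Healthy 3 (adjusted p = 0.0579 to 0.113). In the fit without Healthy 2, 12 of 14 enteroendocrine genes rose and 14 of 24 interferon, 10 of 14 MHC class I, 6 of 8 MHC class II, 11 of 20 cholesterol and 7 of 16 antimicrobial genes fell. There these 6 lists and ion and water transport passed with an estimated correlation (adjusted p = 0.0121 to 0.0401), and absorptive colonocytes did not (0.0971).

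Higher with no member called was unfolded protein response (20 genes, none adjusted over the list alone, median 0.46, camera adjusted p = 0.000848, adjusted p = 0.567 with an estimated correlation). Lower with no member called were oxidative phosphorylation (26 genes, 1 lower adjusted over the list alone, median -0.22, camera adjusted p = 1.14e-05, adjusted p = 0.431 with an estimated correlation), short-chain fatty acid uptake and fatty acid oxidation (25 genes, 3 lower adjusted over the list alone, median -0.28, camera adjusted p = 0.000832, adjusted p = 0.431 with an estimated correlation) and lytic cell death (18 genes, 6 lower adjusted over the list alone, median -0.20, camera adjusted p = 0.00124, adjusted p = 0.0873 with an estimated correlation). Mlkl, the pore-forming protein of necroptosis, was 18.5 ± 1.65 CPM in Healthy and 13.3 ± 1.26 in DSS_AcBb (adjusted p = 0.0601). The medians of oxidative phosphorylation and of fatty acid oxidation were -0.14 and -0.14 without Healthy 2. Also lower with no member called were tight and adherens junctions (20 genes, 3 lower adjusted over the list alone, median -0.15, camera adjusted p = 0.0243, adjusted p = 0.431 with an estimated correlation) and cell cycle (23 genes, none adjusted over the list alone, median -0.25, camera adjusted p = 0.0255, adjusted p = 0.687 with an estimated correlation). Cldn3, a claudin, was 374 ± 40.9 and 276 ± 7.28 CPM (adjusted p = 0.0598). Lower too were crypt stem cell (15 genes, 1 lower and 1 higher adjusted over the list alone, median -0.26, camera adjusted p = 0.0323, adjusted p = 0.431 with an estimated correlation) and xenobiotic and oxidative defence (17 genes, none adjusted over the list alone, median -0.22, camera adjusted p = 0.0323, adjusted p = 0.266 with an estimated correlation). Calls lost when a library was left out were unfolded protein response without Healthy 2 (adjusted p = 0.257), tight and adherens junctions without DSS_AcBb 2 or Healthy 2 (adjusted p = 0.0601 to 0.0846) and cell cycle without Healthy 3, Healthy 1 or DSS_AcBb 1 (adjusted p = 0.113 to 0.539). Others were crypt stem cell without Healthy 1, Healthy 3 or DSS_AcBb 1 (adjusted p = 0.0906 to 0.302) and xenobiotic and oxidative defence without Healthy 3, DSS_AcBb 2 or Healthy 2 (adjusted p = 0.0552 to 0.141). Not called were goblet cell and mucus (camera adjusted p = 0.482), fetal-like regenerative epithelium (0.363, 1 lower and 1 higher adjusted over the list alone), tuft cell (0.801), cytokines and chemokines (0.842, 2 lower adjusted over the list alone), glycolysis and hypoxia (0.842, 1 higher adjusted over the list alone) and wound repair and matrix remodelling (0.722, 2 lower and 2 higher adjusted over the list alone). Median, mean and test differed in sign for goblet cell and mucus, cytokines and chemokines and wound repair. Tnfsf10 and Ccl28, a chemokine of mucosal epithelium, had log2 changes of -1.80 and -0.83 and were called. Egln3, an oxygen-sensing hydroxylase of the glycolysis and hypoxia list, rose by 0.49.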

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

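Removing the mitochondrial genes, and leaving out Healthy 2 for DSS_AcBb minus DSS, were chosen after seeing the data, and the other alternatives were planned. Of 52 alternative counts of genes 18 stayed within 1.5 times the reported one, 12 were higher and 22 lower. Genes called for DSS minus Healthy, DSS_AcBb minus DSS and DSS_AcBb minus Healthy numbered 530, 347 and 1555 with DESeq2, 3390, 6731 and 4795 with limma-voom, 3, 553 and 12 with the 2 compared groups only, and 40, 0 and 107 with the replicate block. DESeq2 included 90 of the 92, the 1 and 234 of the 236 genes called by edgeR, and limma-voom included all of them. At an adjusted p under 0.01 there were 10 for DSS minus Healthy and 6 for DSS_AcBb minus Healthy. Of the 236 genes called at an adjusted p under 0.05 for DSS_AcBb minus Healthy, 124 had an absolute log2 change of at least 1. Leaving out single libraries gave 3 to 534, 0 to 1137 and 4 to 930 genes, the highest each time without Healthy 2. Limma-voom gave Healthy 2 a weight of 0.0662, against at most 5.61. Same-numbered mice of different groups correlated weakly in their deviations from the group means, from -0.0779 (Healthy 3 and DSS 3) to 0.212 (DSS 1 and DSS_AcBb 1), so the paired fit was kept as an alternative. Of 40 counts of lists 34 stayed within 1.5 times. The exceptions were 3, 0 and 3 lists with an estimated correlation and 3, 3 and 8 with fry. Opposite calls numbered 53 with DESeq2 and 0 to 152 without single libraries. Among 1892 values of named genes 1270 kept their side of the threshold, 284 passed it newly, 336 lost it and 2 reversed. Those were Zg16, a goblet cell lectin, in DSS_AcBb minus Healthy, with a log2 change of -2.43, which was 0.65 with limma-voom and ranged from -2.98 to 0.81 without single libraries (0.81 without Healthy 2). Among 587 values of single lists 475 kept their call, 111 lost it and 1 reversed. That was cell cycle in DSS_AcBb minus DSS, whose median ranged from 0.01772 without DSS 1, where the test pointed down, to 0.44 without another library. No scaling moved the median log2 change of all genes by more than 0.05. Each group held 1 closest pair of libraries: Healthy 1 and 3, DSS 2 and 3, and DSS_AcBb 2 and 3. Leaving out the remaining library of a group gave more called genes than leaving out either library of its pair. The cause of the differences between these alternatives was not tested.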

Other observations

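Genes in the first 2 paragraphs, and the tests of explanations after them, were chosen after the results were seen, while the counts over other splits of the libraries were planned. Those genes were not tested as groups of their own. Neurog3, which starts endocrine differentiation, was 5.6 ± 1.68 CPM in DSS and 17.2 ± 3.66 in DSS_AcBb (log2 change 1.63, adjusted p = 0.00932 without Healthy 2 and 0.413 with it). Nkx2-2, Myt1, St18 and Pax4 rose by 1.23, 1.14, 1.09 and 1.23 without Healthy 2 (adjusted p = 0.00666, 0.0259, 0.0374 and 0.008). With all 9 libraries their adjusted p lay between 0.398 and 0.528. In DSS minus Healthy without Healthy 2, none of the 5 was called, with log2 changes of -0.66 to -0.14.

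In DSS_AcBb minus DSS without Healthy 2, Hspb1 rose by 1.36, Hsph1 by 0.78, Dnaja4 by 0.61, Bag3, a co-chaperone, by 0.58 and Hsp90ab1 by 0.43 (adjusted p of 0.00666 to 0.0211). With all 9 libraries their adjusted p lay between 0.328 and 0.677. The heat shock genes Hspa1a and Hspa1b were not called without Healthy 2 (0.41 and 0.39, adjusted p = 0.285 and 0.315). Reg3b, a lectin that binds bacteria, was 590 ± 51 CPM in DSS and 230 ± 101 in DSS_AcBb, and Reg3g 122 ± 3.92 and 55.9 ± 12.6 CPM. Their log2 changes without Healthy 2 were -1.36 and -1.12 (adjusted p = 0.0254 and 0.00582), against adjusted p of 0.522 and 0.536 with it. In DSS minus Healthy without Healthy 2 both were lower as well (-1.78 and -2.06).

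Healthy 2 differed from Healthy 1 and 3 by more than any other library differed from its group. A swap with a colitis library was argued against, since 0 of the 6 DSS and DSS_AcBb libraries were nearer to Healthy 1 and 3 than to their own group, while a single wrong label or a swap with an outside sample stays open. A smaller mitochondrial share multiplies all other genes by 1 factor, and that was argued against as the whole cause. Over the other genes the interquartile range of its log2 differences from Healthy 1 and 3, which such a factor leaves unchanged, was 0.7161, against 0.2 to 0.3981 in the colitis libraries (SD 0.08237). A shared cause of the small share and of the rest stays open. Another sampled position along the colon is a candidate explanation, since the median log2 difference of the distal Hox genes, Healthy 2 minus the mean of Healthy 1 and 3, was 1.268 (Hoxb13 1.27, Hoxa13 1.18, Hoxd13 1.41, Hoxd11 1.43, Hoxa11 -0.60). No biological explanation was tested for it.

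Interferon and MHC class II genes were lower in DSS than in Healthy. Healthy 2 alone was argued against as the source, since the interferon median without it was -1.629 and the MHC class II median -2.31. Fewer leukocytes among the sorted cells, which were selected as negative for CD45, stay open. The 9 of 62 leukocyte markers tested had a median log2 change of -0.0007518 (SE 0.3772), but a marker with no read in any 1 library is missing from the table, so the 9 do not decide it. An effect of colitis itself may remain, as may amoxicillin if the Healthy mice did not receive it, and neither was tested. Colon position was not separated from group here either. The distal Hox list was lower in DSS (median -0.84, and -0.32 without Healthy 2), a call lost with an estimated correlation. Position was not tested as a source of the interferon and MHC class II difference.

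Posterior Hox genes were higher in DSS_AcBb than in DSS. Sampling of another colon position could account for it: the median of Hox groups 10 to 13 exceeded that of groups 1 to 8 by 0.9805 on the log2 scale, and position cannot be separated from group, since all DSS_AcBb libraries are of 1 group. Stromal cells among the sorted cells stay open too. The ratio of Col1a1, a collagen of fibroblasts, to Hoxd13 differed by 14.75 times among the DSS_AcBb libraries (3.004, 0.2036 and 0.5684), but whether stromal cells keep 1 ratio was not measured. Of the 3 fibroblast genes tested, 1 followed the order of Hoxd13 over DSS_AcBb 1 to 3, Fbln1 (6.363, 8.845 and 7.608 CPM). Col1a1 (23.11, 5.005 and 10.45 CPM) and Pdgfrb (3.76, 2.458 and 3.46 CPM) ran the other way. Pdgfrb was below its DSS level of 5.895, 6.875 and 6.207 CPM, against a stromal source. Col1a1 and Fbln1 were above their DSS levels, in the direction of such a source. Those levels were 3.197, 0.8719 and 1.624 CPM for Col1a1 and 4.476, 4.745 and 3.967 CPM for Fbln1. With 3 of 12 markers tested, and these moving apart, the source stays undecided. An effect of the bacteria on these genes stays open and was not tested.

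With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For DSS and Healthy the real split called 92 genes, 1 of the 10 splits called as many, and the highest other called 0. In DSS_AcBb and DSS the real split called 1 gene, 1 split called as many, and the highest other called 0. For DSS_AcBb and Healthy the real split called 236 genes, 1 split called as many, and the highest other called 0. For lists the real splits called 13, 15 and 16, with 2, 1 and 1 splits calling as many and 13, 12 and 14 in the highest other. The lowest other splits called 8, 2 and 8 lists. A list call at the preset correlation is therefore not by itself evidence of a difference between groups. The other split with 13 lists set Healthy 2 with DSS 2 and DSS 3 against the rest.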
